A study of Caenorhabditis elegans with 14 samples.

How the data were processed

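Whole worms of 2 C. elegans strains were profiled by poly(A) RNA sequencing, with RNA extracted in Trizol, selected on oligo(dT) beads and made into stranded libraries, per the labels' protocols. The authors deposited 1 table of FPKM values per gene and library, per the file headers. Cufflinks 2.2.0 is named in the submitters' processing notes; the aligner, the annotation and the genome build are not given in the sources used here, so chromosomes are those of the table and no coordinates are printed. The 14 columns of values were matched to samples by the exact name of each sample in the labels, and 0 columns were left unmatched. In XO hermaphrodite young adults the numbers in the sample titles and source names differ, since the reverted library holds a number in the source names; replicates 1 to 3 here follow the titles.

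The table had 20417 rows, of which 6 repeated others and were removed, leaving 20411 genes. Of these, 22 were empty in every library and 13, of which 12 are mitochondrial and 1 is C25A1.16, had values only in the XX male young adult columns; the remaining 20376 were used. Whether the XX male young adult columns were quantified with other settings is not known; if so, the FPKM scaling would differ between the groups of the young adult comparison. Gene symbols are those of the table, with 19175 IDs matched to a table of current names. Depth is not recorded. The low values of a gene are multiples of a step that falls with depth, and comparing these steps between libraries gave relative depths of 0.224 to 0.919 at L3 and 0.619 to 1.459 in young adults, with XX male young adult replicate 1 set to 1. Low genes are therefore less precise in most L3 libraries. Some abundant genes were listed at exactly 0 in single libraries, such as vit-6 in 2 of the XO hermaphrodite young adult libraries and Y17D7B.10 in 1 of them, and whether these are failed estimates is not known.

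All tests used log2(FPKM + 1), so a fold change is on that scale and understates the change of low genes. Genes with a mean of at least 1 FPKM over the 13 libraries of the 4 groups were tested, 14628 in all. The reverted library stayed out of filters, fits and tests. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, 4 group means, no covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05, for the 2 comparisons of animals, their interaction with stage and the 2 stage comparisons. The 20 gene lists and the X chromosome were tested with camera (preset correlation of 0.01, then an estimated correlation) and fry, adjusted over 105 list tests. Differences of X against autosomes were tested by exact permutation over libraries, two-sided. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the table and drew the figures.

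The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined, and those added later are named in the closing section. The rule took, for each comparison of animals, the 6 largest rises and 6 largest falls among called genes with no overlap between libraries and a mean of at least 10 FPKM in the higher group; up to 2 called members per list and direction; the 3 most abundant called X genes in each direction; and xol-1, her-1, sdc-3, tra-2 and sdc-2 in every group. For the other comparisons it took the 4 largest rises and falls.

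The pipeline was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale, in either direction, among 14628. For the L3 comparison it recovered 24% of the smaller and 79% of the larger changes, with 6 unchanged genes called. For the young adult comparison it recovered 36% and 80%, with 4 unchanged genes called. The simulation did not carry the larger spread of the real L3 libraries. It drew the changed genes only from those above a floor of mean level, so its rates do not cover the lowest genes. It also changed far fewer genes than the real young adult comparison called (4964 higher and 4875 lower). The Benjamini-Hochberg cutoff depends on how many genes change, so these rates do not describe that comparison. Alternatives covered the pseudocount, the filter, 3 scalings (upper quartile, median ratio, quantile), array weights, no trend, a replicate block, fits of only the groups compared, stricter thresholds and leaving out each replicate. For comparisons of 2 groups the replicate block was fitted to only the libraries of those groups.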

Results

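RNA of whole worms was profiled in 2 strains of Caenorhabditis elegans in which sex and X chromosome number are uncoupled. TY2205 animals develop as hermaphrodites with 1 X chromosome (XO hermaphrodites), and CB5362 animals develop as males with 2 X chromosomes (XX males). In wild-type animals the pairing is the reverse. Larvae of the L3 stage were collected 24 h after overnight hatching, and young adults after 44 h at 25 °C. The temperature of the L3 larvae is not given, so where stages are compared a temperature difference cannot be told apart from stage. There were 3 XO hermaphrodite L3, 3 XX male L3, 3 XO hermaphrodite young adult and 4 XX male young adult libraries. A further TY2205 young adult library was labelled by its submitters as reverted and not used, and it enters no comparison here. Expression was deposited as FPKM for 20411 genes, of which 14628 had a mean of at least 1 FPKM over the 13 libraries and were tested. Absolute depth is unknown, but the steps between low values gave each library's depth relative to XX male young adult replicate 1, from 0.224 in XO hermaphrodite L3 replicate 1 to 1.459 in XX male young adult replicate 2. The sums of FPKM ranged from 916127 to 1574087 and did not overlap between the groups at either stage. At L3 they were 1317414 to 1574087 in XO hermaphrodites and 1216741 to 1289639 in XX males. In young adults they were 916127 to 940071 in XO hermaphrodites and 1159056 to 1298816 in XX males. Scaling to a common sum was not run. Because the strain, the sex and the X number differ together between the groups, no comparison below separates them. Since whole worms were used, a difference in expression within cells cannot be told apart from a difference in the share of a tissue. Nothing states that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

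The genes known to be altered in these strains were examined in every group. The xol-1 gene, the X-linked switch that promotes male development and is known to be mutated in both strains, was listed at 0 FPKM in all 13 libraries. The her-1 gene on chromosome V, which encodes a secreted male-promoting protein and is known to be mutated in TY2205, was higher in XO hermaphrodites than in XX males at both stages. At L3 it stood at 20.7 ± 16.6 FPKM (SD, n = 3) against 1.23 ± 0.415 (n = 3), a log2 fold change of 3.04 (SE 0.45, limma adjusted p = 0.00425). In young adults it stood at 27.9 ± 14.1 FPKM (n = 3) against 0.642 ± 0.167 (n = 4), a log2 fold change of 4.02 (SE 0.42, limma adjusted p = 4.4e-06). The sdc-3 gene, which acts in dosage compensation and is also known to be mutated in TY2205, was lower in XO hermaphrodites at both stages. Its log2 fold change was -2.06 (SE 0.16, limma adjusted p = 1.1e-04) at L3, from 4.56 ± 0.69 FPKM in XX males to 0.327 ± 0.0792, and -1.01 (SE 0.15, limma adjusted p = 7.5e-05) in young adults. The L3 p-values rest on a spread shared with the young adult libraries. In a limma fit of only the L3 libraries neither her-1 nor sdc-3 was called (adjusted p = 0.113 for sdc-3). The tra-2 gene, which promotes hermaphrodite development and is known to be mutated in CB5362, did not pass the test at L3 (log2 fold change -0.59, limma adjusted p = 0.171), but was called lower without XO hermaphrodite L3 replicate 1 (-0.98). In young adults tra-2 was higher in XO hermaphrodites, at 36.6 ± 2.61 FPKM against 18.1 ± 1.13 (log2 fold change 0.98, limma adjusted p = 0.00366). The dosage compensation gene sdc-2 likewise did not pass at L3 (-0.44, limma adjusted p = 0.297; called lower, at -0.81, without the same replicate) and was higher in young adults (0.63, limma adjusted p = 0.0425), a call lost in each fit that left out a young adult replicate.

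**Figure D1:**
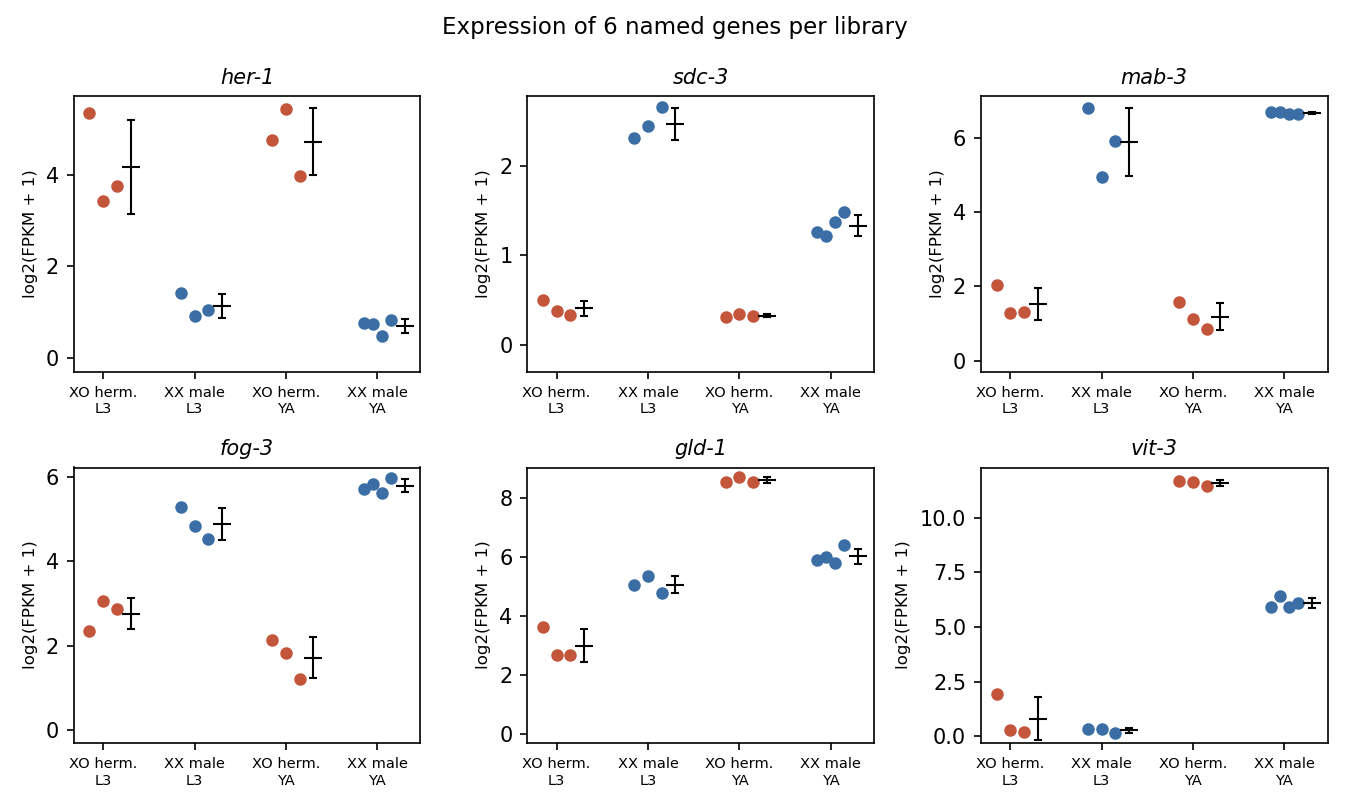
Expression of 6 named genes in each library, as log2(FPKM + 1), in XO hermaphrodites (red) and XX males (blue) at L3 and in young adults (YA); dots are libraries, and the bar beside them is the mean with its SD (n = 3, and 4 for XX male young adults). The libraries of the groups do not overlap for her-1, which averages 20.7 FPKM in XO hermaphrodite L3 and 1.23 FPKM in XX male L3 libraries, nor for sdc-3, mab-3 and fog-3 at either stage.

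The L3 comparison asks how the larvae of the strains differ. Its p-values and counts rest on a spread shared with the less variable young adult groups. In a limma fit of only the L3 libraries no gene named here was called (adjusted p = 0.19 for mab-3 and 0.258 for fog-3). Of the 8 genes of the male tail and mating list 3 were lower in XO hermaphrodite larvae, while the list had a median of -0.10 and did not pass camera (adjusted p = 0.202, and 0.615 with an estimated correlation). Fry, which does not compare a list with all other genes, put the list lower (adjusted p = 6.0e-04). Its members clec-207 and clec-208 reached at most 0.523 FPKM in any L3 library, so the median includes genes hardly detected at this stage. The DM-domain gene mab-3 stood at 1.98 ± 0.944 FPKM against 66.9 ± 40.8 in XX males (n = 3 each; log2 fold change -4.36, SE 0.38, limma adjusted p = 1.4e-04), and dmd-3, which acts in male tail morphogenesis, at 0.433 ± 0.477 against 18.9 ± 13.2 (-3.52, SE 0.49, limma adjusted p = 0.00339; -4.28 without XX male replicate 2). The genes fog-3 and fog-1, which direct germ cells to the sperm fate, had log2 fold changes of -2.12 and -1.38. They belong to the 17 regulators of sex, of which 3 were lower and 1 higher (5 and 1 when adjusted over the list alone). This list had a camera adjusted p of 0.615 with an estimated correlation, and fry put it lower (adjusted p = 0.00977). Germline genes were lower too: 27 of the 43 germline and meiosis genes passed and all 27 were lower (38 when adjusted over the list alone), with the translational regulator gld-1 at 7.37 ± 3.45 against 32.8 ± 6.73 FPKM (log2 fold change -2.07). The chromosome axis gene him-3 was at -2.05. The median of that list was -1.06, against -0.25 for all tested genes. Camera with a preset correlation of 0.01 gave it an adjusted p of 2.6e-18, which became 0.248 with an estimated correlation. Fry, on the same shared spread, put it lower with an adjusted p of 5.1e-05. Its called genes numbered 21 with upper quartile scaling, 24 with median ratio scaling and 14 with quantile normalization, and 15 without XX male replicate 1. None of the 27 stayed called in the fit of only the L3 libraries, or with a replicate block added to that fit.

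Other L3 lists had fewer called genes, under the same limit of the shared spread. No gene named here was called by limma with only the L3 libraries fitted. Among the 30 oocyte and eggshell genes 8 were lower, among them oma-1 (log2 fold change -1.57), and the caveolin gene cav-1 was higher (1.81). When adjusted over the list alone, 15 were lower and 1 higher (camera adjusted p = 0.403 with an estimated correlation). Of the 10 dosage compensation genes 4 were lower (5 when adjusted over the list alone), including sdc-3 and dpy-28 (camera adjusted p = 0.459 with an estimated correlation). Fry put the oocyte and dosage compensation lists lower (adjusted p = 4.0e-04 and 9.1e-04), and no other list of this paragraph passed fry. Of the 131 neuropeptide and insulin genes, 15 were higher and 1 lower (30 and 1 when adjusted over the list alone; camera adjusted p = 0.259 with an estimated correlation). The insulin-like gene ins-13 rose by a log2 fold change of 2.88 and ins-6 was lower at -1.13. Of the 150 collagen genes 5 were higher and none lower, among them dpy-14 at 22.1 ± 7.27 against 1.08 ± 0.586 FPKM and col-74 at 7.58 ± 3.53 against 0.195 ± 0.337 (camera adjusted p = 0.403 with an estimated correlation). The small heat shock gene hsp-12.3 rose by 3.26 and F14D2.5 by 2.85 on the log2 scale, while K08H10.3 was lower at -4.61 (-5.63 and -3.77 without XO hermaphrodite replicates 1 and 2). The sperm gene cpb-1, which encodes an RNA-binding protein, was lower at -3.12, at 0.682 ± 0.305 against 13.7 ± 3.93 FPKM. In 4 lists 1 gene was lower and none higher: cpb-1 in the spermatogenesis list (37 genes), cwp-1 in the male neuron list (7), nhr-25 in the molting list (22; 4 lower when adjusted over the list alone) and clec-206 in the immune list (191; none when adjusted over the list alone). In the vulval list of 13 genes egl-17 passed and was higher (0.89), while the median was -0.49, and when adjusted over the list alone 1 was higher and 4 were lower. None of the 30 major sperm protein genes passed (limma; 0 also when adjusted over the list alone), with a median of -2.33 (camera adjusted p = 2.8e-04, and 0.663 with an estimated correlation). The spermatogenesis list had a median of -1.05 (camera adjusted p = 0.00195, and 0.669 with an estimated correlation). XX male L3 replicate 1 stood apart, with a mean log2 level of 5.64 for the major sperm protein genes against 0.51 and 1.6 in the other XX male L3 libraries. Without this library the medians were -0.73 and -0.27, and neither list passed camera (adjusted p = 0.148 and 0.594). Without XX male replicate 2, which lists msp-76 at 0, msp-76 (-2.74 with every library) and msp-81 (-2.67) were called, at -4.31 and -3.95. Without XX male replicate 1, which holds 127 and 109 FPKM of these genes, they were not called, at -0.81 and -0.82. No member passed in the yolk, body muscle, intestine, heat stress, lipid, ribosomal protein or histone lists. The ribosomal protein list had a median of 0.41 (camera adjusted p = 1.4e-20, and 0.368 with an estimated correlation), which was -0.01 with quantile normalization. The yolk list had a median of 0.63 (camera adjusted p = 0.0221, and 0.552 with an estimated correlation), which was -0.17 without XO hermaphrodite replicate 1. The heat stress list had a median of 1.11 (camera adjusted p = 6.6e-04, and 0.459 with an estimated correlation). The immune, body muscle and histone lists had medians of -0.04, -0.20 and -0.02, below 0, while camera, which compares a list with all other genes, put them on the higher side.

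The counts of called genes in the L3 lists depend on the scaling and on single libraries. With quantile normalization 4 oocyte genes (camera adjusted p = 0.051) and 2 dosage compensation genes were lower, and 10 collagen and 25 neuropeptide genes were higher. With upper quartile scaling 10 collagen and 38 neuropeptide genes were higher. Without XX male replicate 1, 3 oocyte and 1 dosage compensation genes were lower and 3 neuropeptide genes were higher. Without XO hermaphrodite replicate 1, the lower genes numbered 14 in the oocyte list, 8 in the dosage compensation list, 9 in the list of sex regulators, 7 in the vulval list, 8 in the molting list, 8 in the lipid list, 6 in the muscle list, 4 in the intestine list, 3 in the spermatogenesis list and 22 in the immune list. The higher genes then numbered 51 in the ribosomal protein list, 26 in the neuropeptide list, 16 in the collagen list, 9 in the immune list and 5 in the histone list.

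In all, 185 genes were higher and 631 lower in XO hermaphrodite L3 larvae (limma, adjusted p under 0.05; 4046 genes at an unadjusted p under 0.05). Under upper quartile scaling the counts were 506 and 478, and 51.4% of the calls were higher in place of 22.7%; the share was 36.1% with median ratio scaling and 55.6% with quantile normalization. The 4 groups share a single spread in this fit, and the L3 groups vary more (median SD 0.36 and 0.35 on the log2 scale, against 0.18 and 0.20 in young adults). A limma fit of only the L3 libraries called 1 gene higher (hil-7) and 2 lower (nhr-131 and Y17D7B.10), genes named after their values were seen. The rule for named genes also took Y71H2AM.4 (5.32), nspd-4 (-3.66) and ant-1.4 (-3.60). Leaving out 1 library moved these to between 4.57 and 6.82, -4.84 and -2.27, and -4.98 and -2.56, and ins-13 to between 2.2 and 3.81. Of the L3 genes named above and here, Y71H2AM.4, ins-13, nspd-4, ant-1.4, cav-1, cwp-1, egl-17, dpy-28, nhr-25, ins-6 and clec-206 were not called in at least 1 of the fits that leave out a replicate. Leaving out any library moved a count by over 1.5 times, to 66 higher and 179 lower without XO hermaphrodite replicate 2 and to 731 and 3717 without XO hermaphrodite replicate 1. That library stood apart: its Spearman correlations were 0.943 and 0.927 with XX male replicates 2 and 3, against 0.907 and 0.917 with XO hermaphrodite replicates 2 and 3, which correlated with each other at 0.978. Its sdc-3 (0.416 FPKM) and her-1 (39.8 FPKM) lay on the side of its own group.

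In young adults most genes of the germline and male lists differed. All 30 oocyte and eggshell genes were higher in XO hermaphrodites, with a median log2 fold change of 4.82. The gene puf-5, an RNA-binding regulator of oocyte formation, stood at 444 ± 37.3 FPKM (n = 3) against 3.99 ± 0.45 (n = 4), and the eggshell proteoglycan gene cpg-3 had a log2 fold change of 6.38 (SE 0.27). This list also passed camera with an estimated correlation (adjusted p = 0.0359). Of the 6 yolk protein genes 5 were higher (camera adjusted p = 0.459 with an estimated correlation), among them vit-3 at 3100 ± 244 against 67.7 ± 11.3 FPKM (log2 fold change 5.51). The sixth, vit-6, was listed at 0 in XO hermaphrodite replicates 1 and 2 and at 10490 FPKM in replicate 3, and without replicate 3 the list had 5 genes higher and 1 lower. All 30 major sperm protein genes were lower in XO hermaphrodites (median log2 fold change -5.28; camera adjusted p = 0.58 with an estimated correlation), as were 34 of 37 other sperm genes such as gsp-3, a sperm phosphatase gene (-5.68, SE 0.91), and ssp-10 (-5.56). XO hermaphrodite replicate 3 stood apart for major sperm proteins, with a mean log2 level of 6.13 against 4.12 and 3.70, and without it the median was -6.05, with gsp-3 at -6.33 and ssp-10 at -6.30. In the list of other sperm genes W02D9.5 (4.07) and spe-39 (1.03) were higher (camera adjusted p = 0.532 with an estimated correlation). Of the 43 germline and meiosis genes 38 were higher (39 when adjusted over the list alone), including the Notch receptor gene glp-1 at 74.9 ± 8.34 against 6.22 ± 0.988 FPKM and gld-1 at 389 ± 27.3 against 64.5 ± 12.8 (camera adjusted p = 0.368 with an estimated correlation). By fry the oocyte, yolk and germline lists were higher (adjusted p = 1.7e-11, 1.2e-05 and 2.0e-06). The major sperm protein list and the list of other sperm genes were lower (fry adjusted p = 0.00181 and 4.3e-04).

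Male somatic genes were lower in XO hermaphrodite adults without exception among those tested. All 7 male neuron genes were lower (camera adjusted p = 0.0999 with an estimated correlation), with cwp-1, expressed in male ciliated neurons, at 0.681 ± 0.262 against 83.8 ± 12 FPKM. All 8 other male genes were lower (camera adjusted p = 0.248 with an estimated correlation): clec-207 stood at 0.1 ± 0.0866 against 280 ± 43.3 FPKM and clec-208 at 0.0852 ± 0.02 against 217 ± 45.4. Neuropeptide and insulin genes were mostly lower (100 of 131, with 2 higher; camera adjusted p = 0.388 with an estimated correlation). The insulin-like gene ins-31 averaged 654 ± 279 FPKM in XX males and 0.0393 ± 0.0681 in XO hermaphrodites, where flp-23 was listed at 0 in each library (XX males 36 ± 6.14). The immune list, made up mostly of C-type lectins, had 115 of 191 genes lower and 11 higher (camera adjusted p = 0.259 with an estimated correlation), with clec-99 and clec-197 lower at -8.84 and -8.99 and clec-87 and clec-91 higher at 7.04 and 5.64. Muscle genes (10 of 15 lower, among them the troponin gene tni-3 at -3.05; camera adjusted p = 0.459 with an estimated correlation) and intestinal genes (9 of 13 lower, for example pgp-1 at -2.12; camera adjusted p = 0.518 with an estimated correlation) had no member higher as deposited. With quantile normalization 1 intestinal gene was higher and 6 were lower. By fry the male neuron, other male and neuropeptide lists were lower (adjusted p = 3.7e-09, 1.4e-09 and 1.4e-05). The immune, muscle and intestine lists were lower too (fry adjusted p = 5.2e-08, 5.6e-05 and 8.5e-04).

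Among the regulators of sex, 11 of 17 were higher and 3 lower in XO hermaphrodite adults (camera adjusted p = 0.566 with an estimated correlation). The T-box gene sea-1, an autosomal signal of sex determination, was higher at 12.3 ± 3.22 against 0.00764 ± 0.0153 FPKM, and fog-3 was lower at 2.41 ± 1.06 against 54.6 ± 5.96. The dosage compensation list of 10 had 8 genes higher, such as capg-1 (46.3 ± 2.42 against 15.8 ± 2.65 FPKM) and dpy-28 (log2 fold change 1.41), and only sdc-3 was lower (camera adjusted p = 0.599 with an estimated correlation). Of the 150 collagen genes 65 were lower and 9 higher, with col-40 at -3.11 and col-135 at 4.77 (camera adjusted p = 0.617 with an estimated correlation), and 101 lower and 6 higher without XO hermaphrodite replicate 3. Of the 68 histone genes 33 were lower and 5 higher; his-70 fell by 4.77 on the log2 scale, and by 5.39 without XO hermaphrodite replicate 3 (camera adjusted p = 0.0206, and 0.689 with an estimated correlation). With quantile normalization 14 histone genes were lower and 7 higher, and the list did not pass camera (adjusted p = 0.152). By fry the lists of sex regulators and dosage compensation were higher (adjusted p = 5.6e-05 and 4.8e-04) and the collagen list was lower (0.0159). The histone list did not pass fry (adjusted p = 0.0529). Members went both ways in the vulval list (2 higher, 4 lower of 13; lin-3, the epidermal growth factor gene, rose by 2.51), the molting list (2 and 3 of 22), the lipid list (1 and 5 of 19; the lipase gene lipl-5 fell by 2.30) and the ribosomal protein list (1 and 10 of 76). When adjusted over the list alone, the vulval list had 2 higher and 3 lower, the molting list 1 higher and 0 lower, and the ribosomal protein list 0 higher and 4 lower. These 4 lists did not pass camera. Their balance turned with quantile normalization, to 6 higher and 2 lower in the vulval list, 4 and 1 in the molting list, 4 and 2 in the lipid list, and 39 and 3 in the ribosomal protein list, which then passed camera (adjusted p = 0.0088). Of 14 heat stress genes 3 were higher and none lower, but 0 passed when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.461). Its mean log2 level in XO hermaphrodite replicate 3 was 4.56, below each XX male young adult library, against 6.45 and 6.80 in replicates 1 and 2; without replicate 3, 5 genes were higher. The largest rises outside the lists were C08F11.11, D1054.11, W03F11.1, D1054.10, F14H3.6 and Y37D8A.19, with log2 fold changes from 7.19 to 8.08. XX male replicate 4 held most of the male signal of 5 of them, all but F14H3.6, such as 27.7 FPKM of C08F11.11. Without it the fold change of C08F11.11 rose by a further 0.92, and those of D1054.11, W03F11.1 and D1054.10 were 8.59, 8.51 and 8.20. The largest falls were fipr-17 (4230 ± 1220 FPKM in XX males against 1.43 ± 1.29), C48B4.12 (1900 ± 597 against 0.0282 ± 0.0488) and F56C3.8 (2640 ± 727 against 0.949 ± 0.867), with fipr-20, fipr-18 and F46B6.13 at 1240 ± 475, 1190 ± 408 and 1100 ± 300 FPKM in XX males and listed at 0 in each XO hermaphrodite library. In all, 4964 genes were higher and 4875 lower (limma, adjusted p under 0.05), and 75.6% of genes had no overlap between the libraries of the groups, where chance gives 5.7%. The median of all genes was -0.11 as deposited, -0.34 with upper quartile scaling, -0.23 with median ratio scaling and 0.27 with quantile normalization. The medians of the oocyte, yolk, sperm, germline, male, neuropeptide, immune, muscle, intestine, collagen, histone and dosage compensation lists kept their sign under each.

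**Figure D2:**
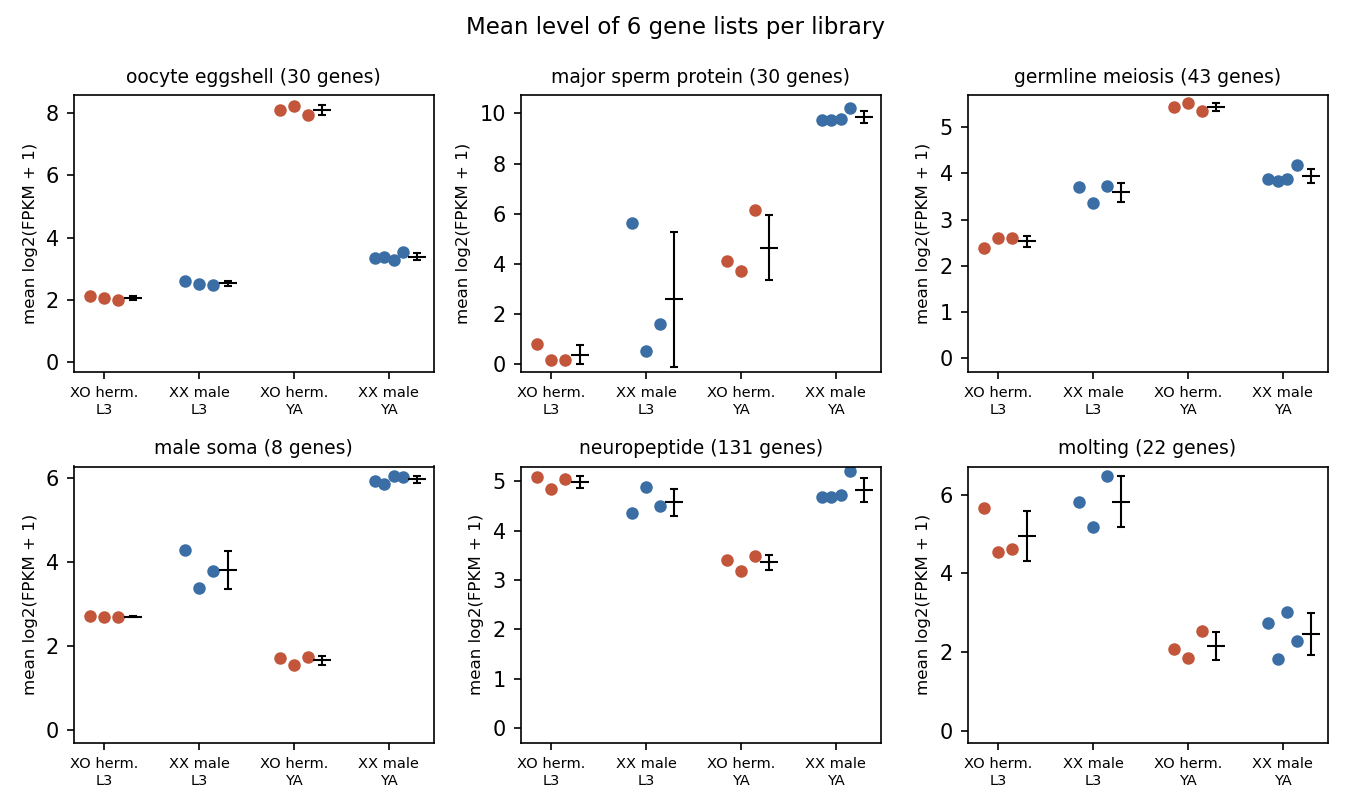
Mean log2(FPKM + 1) of the tested members of 6 gene lists in each library of XO hermaphrodites (red) and XX males (blue) at L3 and in young adults (YA); dots are libraries, and the bar beside them is the mean with its SD (n = 3, and 4 for XX male young adults). The oocyte and eggshell list separates the young adult groups, the major sperm protein list of XX male L3 replicate 1 sits at 5.64 against 0.51 and 1.6 in the other XX male L3 libraries, and the molting list varies between libraries of a group.

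Whether the difference between the animals changed with stage was tested by the interaction of stage and group. The difference became more positive in young adults for 4774 genes and more negative for 3498 (limma, adjusted p under 0.05), and 57.7% of these calls were positive, against 41% with upper quartile scaling and 48.4% with median ratio scaling. All 30 oocyte genes moved upward (camera adjusted p = 0.0359 with an estimated correlation), as did 42 of 43 germline and meiosis genes (adjusted p = 0.259 with an estimated correlation) and all 10 dosage compensation genes (adjusted p = 0.459 with an estimated correlation). Neuropeptide genes moved downward in 92 of 131 cases (adjusted p = 0.276 with an estimated correlation). The most negative interactions outside the lists were those of fipr-17 (-11.12), C48B4.12 (-10.99), fipr-16 (-10.70) and fip-3 (-10.46), of which fipr-16 ranged from -11.54 to -9.28 and fipr-17 from -11.95 to -10.06 when a replicate was left out and fip-3 was -11.11 without XO hermaphrodite L3 replicate 3, and C08F11.11 (7.82), W03F11.1 (7.63) and D1054.11 (7.54) were among the most positive (8.74, 8.49 and 8.16 without XX male young adult replicate 4). The top of that ranking was Y17D7B.10, listed at 0 in all 3 XO hermaphrodite L3 libraries and also in single libraries of both young adult groups; its call was lost in most fits that left out a replicate. Of the 631 genes lower in XO hermaphrodites at L3, 429 were higher in young adults, against 214.1 expected for independent lists (Fisher's exact test, odds ratio 4.43, p = 4.0e-71); the comparisons share no libraries, though genes are not independent. Of the 185 genes higher at L3, 69 were higher and 62 lower in young adults, against 62.8 and 61.7 expected. Across the 14628 genes the log2 fold changes at the stages had a Pearson correlation of 0.18 and a Spearman correlation of 0.04.

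Within each strain, the change from L3 to young adult was measured. In XO hermaphrodites 4936 genes rose and 4162 fell, and in XX males 3174 rose and 4171 fell (limma, adjusted p under 0.05). The adult cuticle collagen gene col-119 rose from 1.71 ± 2.77 to 5650 ± 1380 FPKM in XO hermaphrodites and from 0.216 ± 0.148 to 9370 ± 1300 in XX males. In XX males col-122, col-140 and col-19 also rose, by 12.50, 12.43 and 12.35 on the log2 scale. In XO hermaphrodites the yolk genes vit-2, vit-5 and vit-3 followed col-119, with 11.22, 11.03 and 10.79; without L3 replicate 1, col-119 (11.48 with every library) and vit-2 each rose by 12.28 and vit-5 by 11.74. The larval collagens col-41 and col-90 fell in both strains: col-41 went from 1040 ± 157 to 2.38 ± 3.01 FPKM in XO hermaphrodites and from 1470 ± 549 to 11.9 ± 8.45 in XX males. In XO hermaphrodites the fold changes of col-41 (-8.65) and col-90 (-8.07) were -8.02 and -7.44 without young adult replicate 2, and larger in size without replicate 3 (col-41 -9.36). In XO hermaphrodites F53F1.5 (-7.17; -5.99 and -8.32 without young adult replicates 2 and 3) and col-17 (-6.97; -5.95 and -7.99) fell as well, and in XX males col-54 (-6.28) and K01D12.9 (-5.90, and -6.54 without L3 replicate 2). Molting genes fell in both, 19 of 22 in XO hermaphrodites and 21 of 22 in XX males (camera adjusted p = 0.451 and 0.403 with an estimated correlation). All 43 germline and meiosis genes rose in XO hermaphrodites (camera adjusted p = 0.257 with an estimated correlation), while in XX males 10 rose and 1 fell (camera adjusted p = 0.0213, and 0.663 with an estimated correlation). With median ratio scaling 26 rose in XX males. All 7 male neuron genes rose in XX males (camera adjusted p = 0.0691 with an estimated correlation). Major sperm protein genes rose in both, 28 of 30 in XO hermaphrodites and 30 of 30 in XX males (camera adjusted p = 0.642 and 0.414 with an estimated correlation). Genes that fell in both strains numbered 2070, against 1186.7 expected for independent lists, while those that rose in both numbered 1152, a smaller excess over the 1071 expected (Fisher's exact test, odds ratio 1.15, p = 6.4e-04). These lists too come from 1 fit with a shared spread. The share of rises moved from 54.3% to 35.7% in XO hermaphrodites with upper quartile scaling, and from 43.2% to 62.3% in XX males with median ratio scaling.

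The effect of X dose was addressed by the level of X genes relative to autosomal genes within each library, as the median log2(FPKM + 1) of 1985 X genes minus that of 12643 autosomal genes. At L3 this was -0.18 ± 0.13 in XO hermaphrodites and -0.27 ± 0.11 in XX males (SD, n = 3 each), a difference of 0.10 (exact permutation test, two-sided p = 0.4, where 0.1 is the smallest p this design allows). In young adults it was -1.40 ± 0.01 (n = 3) and -0.95 ± 0.04 (n = 4), a difference of -0.45 (exact permutation p = 0.0571, the smallest this design allows). Both stages in an exact permutation test stratified by stage gave a mean difference of -0.17 (p = 0.0829 over 700 assignments). This depended on the genes used: by the same exact permutation test it was -0.54 (p = 0.0286) with a mean of at least 5 FPKM, 0.21 (p = 0.0371) without a filter, and -0.25 (p = 0.0343) with autosomal genes matched on expression. Over genes at least as high in L3 as in young adults it was -0.16 (exact permutation p = 0.00571, and 0.0457 adjusted over 8 settings), but these genes were picked partly by the levels compared, so this p is no independent test. The last 2 settings were chosen after the data were seen, and the other p-values are not adjusted for the number of settings. X genes were underrepresented among the genes higher in XO hermaphrodite adults (11.2% of X genes against 37.5% of autosomal genes; Fisher's exact test, adjusted p = 1.3e-135) and overrepresented among the lower ones (46.2% against 31.3%, adjusted p = 2.5e-37). Genes are not independent, so these p-values overstate the evidence: as a list, X genes passed camera with the preset correlation (adjusted p = 2.2e-05) and not with an estimated one (0.58). Fry put the X list lower (adjusted p = 0.00657). The counts of 223 X genes higher and 917 lower became 437 and 641 with quantile normalization and 185 and 1162 with upper quartile scaling. The most abundant X genes among these calls were the yolk genes vit-2, vit-5 and vit-4, which were higher, and col-181, F46H5.3 and act-4, which were lower. Chromosomes I and III had the largest shares of genes higher in XO hermaphrodite adults, at 45.4% and 46%. At L3, 1.5% of X genes and 1.2% of autosomal genes were higher, and 2.7% and 4.6% were lower, so X genes were underrepresented among the lower ones (Fisher's exact test, odds ratio 0.585, adjusted p = 1.1e-04), under the same limit on independence. As a list, X genes did not pass camera at L3 (adjusted p = 0.751, and 0.967 with an estimated correlation). The balance at L3 turned with the scaling, from 29 X genes higher and 54 lower to 67 and 19 with quantile normalization and 77 and 40 with upper quartile scaling. Without a filter on low genes the young adult difference was 0.37 in place of -0.45. With a mean of at least 5 FPKM it was -1.08, and the L3 difference was -0.01.

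**Figure D3:**
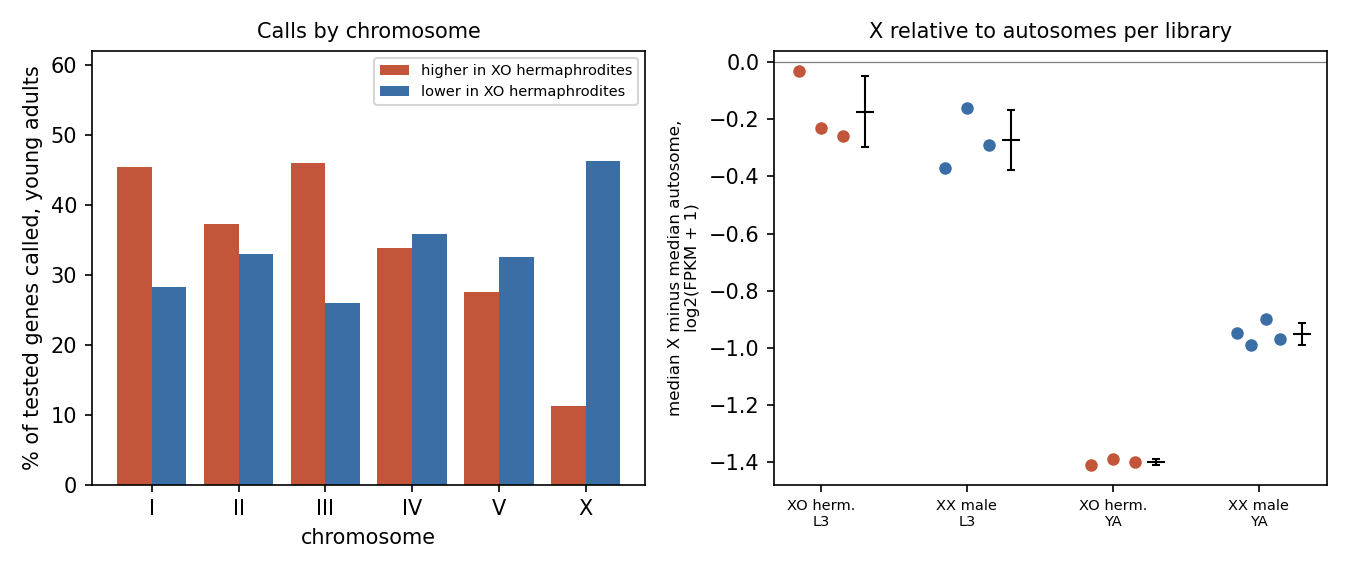
Left, the percentage of tested genes on each chromosome that were higher (red) or lower (blue) in XO hermaphrodite than in XX male young adults; right, the median log2(FPKM + 1) of X genes minus that of autosomal genes in each library, with the mean and SD beside the dots (n = 3, and 4 for XX male young adults). X has 11.2% of its genes higher and 46.2% lower, and the young adult libraries lie at -1.40 on average in XO hermaphrodites and at -0.95 in XX males.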

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

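All tests of explanations in this part were chosen after the results they concern had been seen.

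The difference between the animals changed with stage, by the test of the interaction, for 4774 genes upward and 3498 downward. Among these, 429 genes were lower in XO hermaphrodites at L3 and higher in young adults, with both differences called, and 62 went the opposite way. Of the 129 named genes tested, 83 had a called interaction.

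Regrouping the libraries at random asks whether as many calls arise without the real groups. For the young adult comparison, 1 of 35 splits, the real split itself, gave as many genes (9839, the highest other 5635). This share lies under 0.05, but it is the smallest that 35 splits allow and is not adjusted for the number of comparisons regrouped. Chance differences between cultures were not addressed, since nothing states that the replicates came from separate ones. The same holds for the stage comparison in XX males (1 of 35; 7345 against 2868). For the interaction, 2 of 100 drawn splits, the real one included, reached the real 8272 and the highest other gave 8656. That other split kept the young adult groups and regrouped only L3 libraries, so the small share is set by the young adult difference. With the young adult groups kept, 3 of the 20 assignments of the L3 libraries gave as many genes, so chance is not excluded for the part that the L3 grouping adds. With 3 libraries in each group there are 10 splits, too few for a share under 0.05: at L3, 2 splits gave as many genes as the real 816, and the highest other gave 1378. That other split sets XO hermaphrodite replicate 1 and XX male replicates 1 and 3 against the remaining L3 libraries. The mean log2 level of the molting list separates the same sets: 5.67, 5.81 and 6.48 against 5.17 in XX male replicate 2 and 4.54 and 4.62 in XO hermaphrodite replicates 2 and 3. These samples thus have a structure besides the group, and its cause was not tested. For the stage comparison in XO hermaphrodites 1 of the 10 splits, the real one, gave as many genes (9098 against 1).

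XX male L3 replicate 1 had high sperm genes, with major sperm proteins at a median of 5.67% of their XX male young adult level and other sperm genes at 7.39%. Admixture of young adult male RNA is argued against by the adult cuticle collagens, whose median was 0.0283% of the adult level over 16 genes (upper quartile 0.083%, against a lower quartile of 3.43% for the major sperm proteins). Older animals in that culture may be the source, but the test left this open: 10 of the 15 male tail and neuron genes were higher in this library than in both other XX male L3 libraries, short of the 12 set as the bound. No library of an intermediate stage was included. No biological explanation was tested, as the design gives none for a single library.

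Germline and meiosis genes were lower in XO hermaphrodite larvae, by a median of -1.06. Scaling of the libraries is argued against as the whole cause, because with upper quartile scaling, which brought the median of all genes from -0.25 to -0.03, the median of the list was -0.86. The mean level of the list then differed by -0.84 between the L3 groups, with no overlap of libraries and SDs of 0.31 in XO hermaphrodites and 0.13 in XX males (0.12 and 0.21 as deposited). Called genes went from 27 to 21, and to 14 with quantile normalization, where the mean level differed by -0.76. In a limma fit of only the L3 libraries none of the 27 stayed called. Replicate 1 of the XX males is argued against too, since without it the median was -1.04, although the number of called genes went to 15. A difference in developmental age between the L3 groups may contribute and cannot be told apart from the groups: the molting list differed by -0.88 between the groups, with an SD of 0.63 in XO hermaphrodites and 0.66 in XX males and overlapping libraries. With an estimated correlation the germline and meiosis list did not pass camera (adjusted p = 0.248), while fry, on the shared spread, put it lower (adjusted p = 5.1e-05). The sex, X number and strain of the animals stay open as untested explanations.

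X genes were lower relative to autosomes in XO hermaphrodite adults, by -0.45. X number acting alike at both stages is argued against as the whole cause by the L3 difference of 0.10, which lies above the adult one by more than 2 times 0.13, the larger SD of the L3 groups. Genes that rise from L3 to young adult, such as germline genes, may account for part: over the genes at least as high in L3, the differences were alike, -0.16 at L3 and -0.15 in young adults, which goes with an effect of X number for these genes. This decides nothing, because the genes were picked partly by the adult levels that are then compared, and the L3 difference of 0.10 counts only against X number as the cause of the full -0.45. The adult difference also depends on the filter (-1.08 with a mean of at least 5 FPKM, 0.37 without a filter). It was -0.43 without members of the major sperm protein, sperm, oocyte and germline lists, but 12503 of the 12643 autosomal genes stayed, so this left out few genes. What share comes from the germline, the sex or the X number cannot be told apart, since these differ together between the groups.

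In XX male young adults, the group with 4 libraries, 28 of 149 values (129 named genes and 20 list means) had a library whose gap to the nearest of the others exceeded the limit for 4 values, where chance gives about 1 in 20. Replicate 4 held most of them. It was the highest for cpb-1 (65.5 FPKM), msp-76 (4030), dpy-28 (14.4), C08F11.11 (27.7), D1054.11 (15.9), W03F11.1 (13.3), D1054.10 (8.97), Y37D8A.19 (27.8), glp-1 (7.7), cwp-2 (114), sea-1 (0.0305), ins-31 (1070), cpr-1 (3740), clec-91 (5.07), clec-197 (752) and clec-99 (703), and the lowest for hsp-60 (87) and tra-1 (43.9). Its mean log2 level was also the highest for the major sperm protein list (10.20), the spermatogenesis list (6.14), the germline and meiosis list (4.18), the neuropeptide list (5.20) and the intestine list (6.88). Replicate 3 was the highest for rpl-29 (32800 FPKM) and the ribosomal protein list (11.19) and the lowest for C49F5.7 (117). Replicate 2 was the highest for lin-31 (6.33) and the lowest for sdc-2 (0.688).

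The library that the submitters call reverted lies outside the comparisons and has a signal in 3 genes of interest. Its sdc-3 was 17.7 FPKM, its her-1 74.7 FPKM and its xol-1 0.672 FPKM, where the 3 XO hermaphrodite young adult libraries average 0.251 for sdc-3 and 27.9 for her-1 and are listed at 0 for xol-1.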

How the results depend on the processing

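The following were chosen after seeing the data: leaving out XX male L3 replicate 1 and XO hermaphrodite young adult replicate 3 together, setting zeros of abundant genes as missing, the genes at least as high in L3, the matching on expression, and 2 of the scalings of gene lists. The young adult and interaction counts stayed within 1.5 times under every alternative run. The L3 counts, 185 higher and 631 lower, did not: they were 506 higher with upper quartile scaling, 341 higher with median ratio scaling, 391 and 312 with quantile normalization, 812 and 4311 with array weights, 40 and 135 at an adjusted p under 0.01, 65 and 155 without both doubted libraries, and 1 and 2 with only the L3 groups in the fit; with a fold of at least 2, 363 were lower. With only the L3 groups, 1813 genes had an unadjusted p under 0.05, and the causes of these shifts were not tested. The stage comparison in XO hermaphrodites had 6295 genes lower with upper quartile scaling, and that in XX males had 2640 lower with median ratio scaling and 2274 with a fold of at least 2. Leaving out each replicate gave 66 to 731 genes higher and 179 to 3717 lower at L3, 4577 to 4958 and 4224 to 4684 in young adults, 4415 to 5447 and 2979 to 3535 for the interaction, 4487 to 5235 and 3645 to 4182 for the stages of XO hermaphrodites, and 2969 to 3067 and 3313 to 4194 for those of XX males; the X difference ranged from 0.03 to 0.16 at L3 and from -0.46 to -0.43 in young adults. Of 34 named L3 calls 18 held without each replicate, and of 77 young adult calls 66 did. None of the 34 was called with only the L3 groups in the fit, which kept 2 of all 816 L3 calls. A replicate block added to that fit kept 0.

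The replicate block is not part of the design, and for 2 groups it was fitted to only their libraries, without the spread shared over 4 groups. The L3 counts were then 0 higher and 1 lower (limma, 1350 genes at an unadjusted p under 0.05). The young adult counts were 5602 and 5641, and the X differences 0.10 and -0.45. The same fits without a block gave 1 and 2 at L3 and 5530 and 5638 in young adults, so the loss of L3 calls cannot be put down to the block. Same-numbered L3 samples deviated with correlations of -0.06, -0.05 and -0.02, and the young adult pairs with 0.05, 0.3 and 0.2; pairing by number was not assumed, because not every pair exceeded 0.1. The X difference was -0.01 at L3 with a mean of at least 5 FPKM, -0.16 at L3 over genes at least as high in L3, and 0.37 in young adults without a filter (-1.08 there with at least 5 FPKM); the cause was not tested. Gene lists that passed in the main or the alternative test changed direction in 5 cases: the L3 immune (-0.04) and histone (-0.02) lists by fry, and the ribosomal protein list with quantile normalization at L3 (-0.01), in young adults (0.45) and in the interaction (0.50). The L3 body muscle and X chromosome lists also differed in sign between camera and fry, but passed neither. Camera compares a list with all other genes and fry does not, so their signs can differ without a change in processing. Depth differs between libraries and absolute depth is unknown, so zeros of low genes cannot be read as absence.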

Other observations

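The tests of this part were chosen after the data had been seen. Gene families defined by symbol were compared in young adults, with 244 tests, each family of at least 8 tested genes in both directions (Fisher's exact test, adjusted over these). Nuclear pore genes (npp) were higher in XO hermaphrodites in 22 of 22 cases, with a median log2 fold change of 1.70 (adjusted p = 2.8e-09), and Mediator genes (mdt) in 19 of 20 (1.47, adjusted p = 7.8e-07). RNA polymerase II subunit genes (rpb) were higher in 11 of 11 (adjusted p = 1.5e-04), TATA-binding protein associated factor genes (taf) in 15 of 17 (adjusted p = 1.4e-04), and chaperonin genes (cct) and exosome genes (exos) in 8 of 8 each (adjusted p = 0.00214). The nspc family was higher in 16 of 18 genes, with a median of 2.86 (adjusted p = 7.5e-05). On the other side, FMRFamide-like peptide genes (flp) were lower in 30 of 30 (median -1.82, adjusted p = 3.7e-13), other neuropeptide-like genes (nlp) in 28 of 41 (adjusted p = 1.3e-04), ligand-gated ion channel genes (lgc) in 18 of 26 (adjusted p = 0.00226) and the nspd family in 9 of 9 (median -5.11, adjusted p = 9.5e-04). C-type lectins (clec) were lower in 98 of 150 (adjusted p = 2.1e-13). Genes of a family are not independent of each other, so these p-values describe how calls fall over families.

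The reverted library correlated across genes with the XO hermaphrodite young adult libraries at a Spearman correlation of 0.931 to 0.983, and with the XX male young adult libraries at 0.509 to 0.524. Of the 13 genes with values only in the XX male young adult columns, 12 are mitochondrial and none could be compared between the groups. XO hermaphrodite young adult replicate 3 had a mean log2 level of 6.13 for major sperm proteins against 4.12 and 3.70 in replicates 1 and 2, and of 4.56 for heat stress genes against 6.45 and 6.80.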
